A study of Mus musculus with 6 samples.

How the data were processed

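Polyadenylated RNA was sequenced from mouse embryonic handpads, the paddle-shaped ends of the forelimbs, at embryonic day 14.5. The labels give C57BL/6 mice, a stranded Illumina mRNA library kit, 3 wild-type samples and 3 Grhl3 knockout samples. The labels do not say that the replicates were separate embryos or pools, so the p-values measure the spread between these samples, which may be technical in part.

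Per the submitters' processing notes, the tools were FastQC and kallisto, which assigns reads to transcripts without a base-by-base alignment, and the genome build was mm10. The kallisto version and the transcript set are not given in the sources used here. Per the file headers, each of the 6 deposited transcript tables gives the length, the effective length, the estimated count and the TPM, a length-corrected share of the library, of 111462 transcripts. The deposited estimated counts are not normalized, and they hold fractions where reads were shared between transcripts. The deposited TPM values were not used for any test. The authors' deposited table of the comparison gives a log2 fold change, a log2 CPM, a likelihood ratio score, a p-value and a false discovery rate (FDR) per gene, per the file headers. Its name gives edgeR as the tool, and it lists 941 genes with p-values up to 0.0506.

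Transcripts were matched to GENCODE mouse annotation of the same genome build by their unversioned identifiers. Of the transcripts, 110203 matched, 107706 of them with the same version, and 1259 did not match. The unmatched transcripts held 0.504% to 0.566% of the counts of a library and stayed out of the gene tests. Estimated counts were summed over the transcripts of a gene and rounded to whole numbers, which gave 34989 genes. Summing removes the division of reads between isoforms of a gene, but reads shared between near-identical genes remain divided as kallisto divided them. Values of such genes are uncertain, among them Krt6a, Krt6b, Krt16, Krt17, the Sprr2a genes, BC100530, Ifi202b, Xlr3b and the ribosomal protein pseudogenes.

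The libraries held 38052692 to 56037639 estimated counts. Reads without molecular identifiers are not independent molecules, so floors cover counting error only. A group at 0 was given a floor of 3 counts over its 3 libraries together. Counts were put on the CPM scale with library sizes scaled by TMM, except the sum of Y-linked genes, which used plain library totals.

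Knockout and wild-type were compared with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test (glmQLFit and glmQLFTest) with genotype as the only term. Genes passed filterByExpr with a minimum count of 10 and a minimum total of 15, which left 16938 genes. P-values were adjusted by Benjamini-Hochberg, and a gene was called at an FDR under 0.05. Fold changes are knockout minus wild-type on the log2 scale, with standard errors (SE) from the fit. The script was tested on simulated counts drawn for the same 16938 genes with 3 libraries per group. In 5 runs with 200 changed genes each, the script recovered 19.4% of genes changed 1.5-fold, 62.1% of those changed 2-fold and 89.4% of those changed 4-fold. Of its calls, 8.5% were false, which is above the nominal 5%. Each run also raised the 18 genes of the periderm list, described below, by 2-fold, and calls of these counted as true.

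Before the data were examined, 27 gene lists were fixed from textbook knowledge of skin, limb and blood cell types and of epithelial pathways. Each list except the sex-linked one was tested with camera from limma 3.58.1, with a preset correlation between genes of 0.01, and adjusted over 26 lists. The sex-linked list was only described. Camera with an estimated correlation and fry were run beside it. Members called are given over all genes and adjusted over the list alone. A liver and visceral endoderm list was written after albumin and alpha-fetoprotein had been seen.

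Genes named in the text follow a rule fixed at the same time. It takes Grhl3, Grhl1 and Grhl2, and up to 12 genes each with the largest rise and fall among called genes with a mean log2 CPM of at least 1, no overlap between the groups, and a symbol that is not a model name. It also takes up to 4 members of each list with the smallest p-values. Genes named outside this rule are marked as chosen after their values were seen. The values of 1 gene that the rule takes are not reported here.

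Alternatives fixed at the same time were other scalings, other filters, effective length offsets, the replicate number as a block, each library left out, DESeq2 1.42.0, limma-voom, the exact test of edgeR, other thresholds and a test per transcript. Alternatives added after the data were seen were the likelihood ratio test, robust dispersion, a term for Y-linked expression, a term for mean transcript length, the removal of pairs of libraries, and scaling on the pan-epithelial list. Removing a pair leaves 1 library in a group, which is then assumed to vary like the libraries of the other group. Replicates of a group differed by more than sampling noise, with chi-square values per degree of freedom between 28.5 and 124.1, so none was counted as a repeat of another. Tables were handled with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.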

Results

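The transcriptome of the mouse handpad was measured at stage E14.5 (embryonic day) in 3 wild-type and 3 Grhl3 knockout samples. Grhl3 is a grainyhead-like transcription factor of surface epithelium. The series asks how epithelial migration and the periderm, the flat outer cell layer of embryonic skin, take part in the separation of the digits. The wild-type libraries held 39587367, 48984542 and 38052692 estimated counts and the knockout libraries 50347529, 47642524 and 56037639. Wild-type replicate 1 stood apart from the other libraries. It had the highest share of ribosomal protein counts, 9.0% against 5.69% to 7.84%, and the lowest mean transcript length per count, 3148 bases against 3347 to 3625 bases. Its log2 CPM correlated at 0.973 and 0.975 with wild-type replicates 2 and 3, and at 0.971, 0.978 and 0.979 with the knockout libraries. On the first principal component, the main axis of variation (33.1%), wild-type replicates 2 and 3 lay at -37.2 and -40.8. Wild-type replicate 1 and the knockout libraries lay there at 12.6 to 26.2. The second (31.5%) put the wild-type libraries at -3 to 53.3 and the knockout libraries at -33.7 to -11.8.

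Grhl3 (ENSMUSG00000037188.7, chromosome 4, 135541888 to 135573630, mm10) was lower in all 3 knockout libraries than in any wild-type library. It measured 14.3, 45.7 and 18.5 CPM in the wild-type libraries and 3.11, 2.86 and 2.95 CPM in the knockout libraries. It fell by 3.14 on the log2 scale (SE 0.41, adjusted p = 0.0221, edgeR quasi-likelihood test). The sources used here do not say which part of the gene was deleted, so the remaining counts cannot be placed against the deletion. Its relatives Grhl1 and Grhl2 did not pass the test, with log2 fold changes of 0.37 and 0.36 (adjusted p = 0.785 for both, edgeR). With libraries scaled on the pan-epithelial list they were -0.13 and -0.1, above the median of all genes, which that scaling put at -0.528, against -0.004. Grhl1 and Grhl2 belong to that list and helped to set the scale, so these values do not test whether they changed. The Grhl3 call was lost when wild-type replicate 3 (adjusted p = 0.0806), knockout replicate 1 (0.162), knockout replicate 2 (0.0759) or knockout replicate 3 (0.121) was left out of the edgeR fit, at log2 fold changes of -3.35, -3.17, -3.12 and -3.13. Over all alternatives the adjusted p ran from 1.7e-10 with the likelihood ratio test to 0.635 without knockout replicates 1 and 2 together, a fit in which 1 knockout library remained and was assumed to vary like the wild-type libraries.

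Genes of the periderm, of keratinocytes at wound edges and of the cornified layer were among the largest changes, and those named here were higher in the knockout. Cdsn, which encodes corneodesmosin, an adhesion protein of cornified cells, rose from 0.151 ± 0.0908 to 18.8 ± 9.54 CPM (SD, n = 3 per group). Klk7, a protease that cleaves corneodesmosin, rose from 0.452 ± 0.123 to 35.2 ± 18.6 CPM (SD, n = 3). Krt6a and Krt17, keratins of periderm and wounded epidermis, rose to 267 ± 122 and 352 ± 102 CPM from 17.8 ± 2.49 and 35.4 ± 11.8 CPM (SD, n = 3). Of 16938 genes tested, 73 changed, 59 higher and 14 lower in the knockout (edgeR quasi-likelihood test). In all 73 the groups did not overlap, against 12.9% of all tested genes and 10% by chance for 3 against 3. The 73 were called on these same libraries, so their separation is no added support. At an unadjusted p under 0.05 there were 1223 genes. The count became 206 without wild-type replicate 1 (70 lower), 45 without wild-type replicate 2 (13 lower) and 10 without wild-type replicate 3 (1 lower). It was 17 without knockout replicate 1 (1 lower), 64 without knockout replicate 2 (4 lower) and 22 without knockout replicate 3 (2 lower). All 73 genes kept the sign of their fold change in each of these fits. Since their groups did not overlap, leaving out a library could hardly change a sign, so this adds no evidence. Without wild-type replicate 1, the remaining wild-type libraries all had Y-linked expression and no knockout library did. In that fit, here and below, genotype cannot be told apart from embryo sex.

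**Figure D1:**
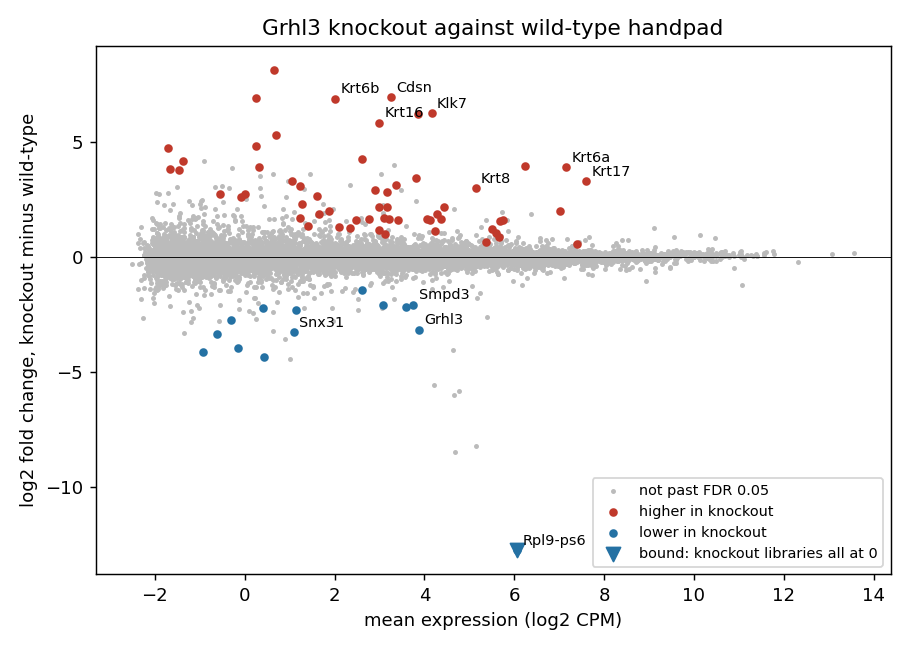
Log2 fold change, knockout minus wild-type, against mean log2 CPM for the genes tested. Red points are the 59 genes higher and blue points the 14 genes lower in the knockout at an FDR under 0.05. Rpl9-ps6 (triangle), at 0 counts in the knockout, is drawn at its lower bound of 6792-fold and was named after its values were seen.

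The 12 genes with the largest rises under the naming rule were Cdsn, Krt6b, Klk7, Krt79, Krt16, Krt13, BC100530, Krt6a, Krt75, Plet1, Krt17 and Ifi202b. Their log2 fold changes ran from 6.95 (SE 0.55, adjusted p = 0.00241, edgeR) for Cdsn to 3.12 (SE 0.24) for Ifi202b. BC100530, a stefin-like gene, went from 9.03 ± 3.5 to 142 ± 61.2 CPM (SD, n = 3). BC100530 and Ifi202b have close relatives in the genome, so the division of their reads is uncertain. Only 7 genes qualified among the falls. Besides Grhl3 they were Snx31 (log2 fold change -3.25), Ceacam19 (-2.28), Xlr3b (-2.15), Lipm (-2.09), Smpd3 (-2.07) and Rdh12 (-1.43), each with an adjusted p between 0.0187 and 0.0466 (edgeR). Snx31 went from 3.83 ± 2.09 to 0.400 ± 0.0396 CPM (SD, n = 3). Xlr3b is an X-linked gene with near-identical copies, and its reads may be divided between them.

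Of 33 keratin genes tested, 13 rose and 0 fell (edgeR), while Krt4 and Krt77 were lower at an unadjusted p under 0.05 and the likelihood ratio test and DESeq2 each called 1 lower. Krt8 and Krt18, the keratin pair of simple epithelia, rose from 7.89 ± 0.877 to 62.7 ± 17.4 CPM and from 8.37 ± 1.8 to 30.7 ± 6.58 CPM (SD, n = 3). Krt16 and Krt6b, which are induced in wounded skin, rose from below 1 CPM to 15.4 ± 8.44 and 7.79 ± 5.39 CPM (SD, n = 3). Krt13, a keratin of mucosal epithelia, rose to 11.5 ± 5.58 CPM and Krt75, a hair follicle keratin, to 25.4 ± 5.12 CPM (SD, n = 3). Krt19 and Krt20, also keratins of simple epithelium, did not pass the test, with log2 fold changes of 0.59 (adjusted p = 0.47) and 1.84 (adjusted p = 0.269, edgeR). Krt4, a periderm keratin, did not pass the test (log2 fold change -1.75, adjusted p = 0.0785, edgeR). It measured 55.8 ± 24.3 CPM in wild-type and 16.6 ± 5.06 CPM in knockout libraries (SD, n = 3). Krt4 passed without wild-type replicate 1 (adjusted p = 0.0172, edgeR), where genotype followed Y-linked expression. Krt1 and Krt10, the keratin pair of the spinous layer, did not pass the test either, with log2 fold changes of 0.03 and 0.31. Krt4, Krt77, Krt19, Krt1 and Krt10 were chosen after their values were seen. The number of keratins that rose was 4 without wild-type replicate 3, 7 without knockout replicate 1 and 8 without knockout replicate 3. Krt6a, Krt6b, Krt16 and Krt17 are similar in sequence, and their single values are uncertain.

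**Figure D2:**
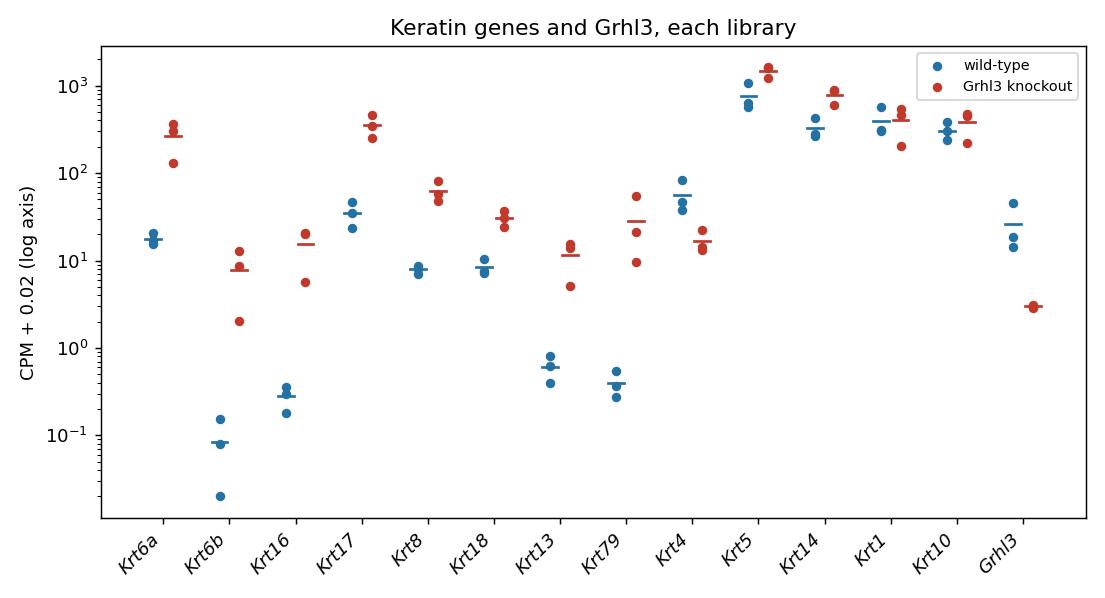
CPM plus 0.02 on a log axis for 13 keratin genes and Grhl3 in each library. Points are libraries, and horizontal lines are group means (n = 3). Krt4 and Grhl3 lie lower in the knockout libraries, Krt1 and Krt10 overlap between the groups, and the other keratins shown lie higher in all 3 knockout libraries.

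Among the 18 periderm genes fixed in advance, 7 rose and 0 fell over all genes, and 13 rose and 1 fell adjusted over the list alone. The members that rose were Krt8, Krt17, Krt6a, Krt18, Krt13, Cldn6 and Krt7, the last of which was named after its values were seen. The median log2 fold change of the list was 0.89, and the list was higher in the knockout with camera (adjusted p = 3.59e-48, and adjusted p = 0.17 with an estimated correlation). The mean log2 CPM of its members was 3.72, 4.32 and 3.82 in the wild-type libraries and 5.49, 4.83 and 5.19 in the knockout libraries. The number of members that rose was 2 without wild-type replicate 3, 3 without knockout replicate 1 and 4 without knockout replicate 3. Without knockout replicates 1 and 2 together it was 4, and without wild-type replicates 2 and 3 together it was 5. Each of these fits left 1 library in a group, so its spread came from the 3 libraries of the other genotype alone.

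Of 37 cornified envelope symbols listed, 20 were tested. Among these 20 genes, 4 rose and 0 fell, and 9 rose and 2 fell adjusted over the list alone. At an unadjusted p under 0.05, 10 were higher and 2 lower, and 7 had negative fold changes. Those that rose were Cdsn, Klk7, Sprr2a1, a small proline-rich precursor of the envelope, and Klk5, a protease of the same family as Klk7. The median log2 fold change was 0.59 (camera adjusted p = 3.08e-16, and adjusted p = 0.237 with an estimated correlation). The number that rose was 2 without wild-type replicate 3. The median was 0.30 without knockout replicate 1 and 0.07 with libraries scaled on the pan-epithelial list, where that of all genes was -0.528. With that scaling 6 cornified genes rose and 2 fell, and 6 rose and 6 fell adjusted over the list alone. Of 25 barrier lipid genes, 2 fell and 0 rose, 4 fell adjusted over the list alone, and 10 had positive fold changes. The 2 called over all genes were Lipm, an epidermal lipase, from 13.7 ± 3.15 to 3.23 ± 1.45 CPM, and Smpd3, a sphingomyelinase also known from bone and cartilage, from 21.7 ± 8 to 5.16 ± 1.63 CPM (SD, n = 3). The median log2 fold change of that list was -0.12 (camera adjusted p = 0.000964, and adjusted p = 0.299 with an estimated correlation). That median was -0.20 without wild-type replicate 1, -0.29 without knockout replicate 1, -0.03 without wild-type replicate 2 or knockout replicate 2, and 0.05 with a term for Y-linked expression. With pan-epithelial scaling 6 barrier lipid genes fell, and 13 adjusted over the list alone, at a median of -0.64. The camera call was lost without knockout replicate 2 (adjusted p = 0.057). The number that fell was 0 when wild-type replicate 3, knockout replicate 1, knockout replicate 2 or knockout replicate 3 was left out, and 1 without wild-type replicate 2. Of 22 spinous layer genes, Krt80 and Serpinb5 rose and 0 fell, and 6 rose adjusted over the list alone, with a list median of 0.32 (adjusted p = 0.285 with an estimated correlation). The number of spinous genes that rose was 0 without wild-type replicate 2, wild-type replicate 3, knockout replicate 1 or knockout replicate 3, and 4 without knockout replicate 2. Adjusted over the list alone 3 rose without wild-type replicate 3 or knockout replicate 1, and the spinous median was 0.21 without wild-type replicate 1 and 0.18 without knockout replicate 1.

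Of 20 pan-epithelial genes, Cldn7 alone rose and 0 fell (edgeR), and 9 rose adjusted over the list alone, or 3 without wild-type replicate 3 or knockout replicate 1. Cldn7, a claudin, went from 2.93 ± 0.476 to 7.07 ± 0.842 CPM (SD, n = 3). At an unadjusted p under 0.05, 10 pan-epithelial genes were higher and 0 lower, and 5 had negative fold changes. The list had a median log2 fold change of 0.47 (camera adjusted p = 1.06e-11, and adjusted p = 0.273 with an estimated correlation). Its mean log2 CPM was 4.04, 4.68 and 4.18 in the wild-type libraries and 4.94, 4.61 and 4.79 in the knockout libraries, so wild-type replicate 2 lay within the knockout range. The number of pan-epithelial genes that rose was 5 without wild-type replicate 2 and 0 without wild-type replicate 3 or any 1 knockout library. Of 19 basal epidermis genes, 0 were called with edgeR over all genes and 6 rose adjusted over the list alone. At an unadjusted p under 0.05, 9 were higher, and the likelihood ratio test called 4 and DESeq2 5. Without wild-type replicate 2, 3 basal genes rose, and 16 adjusted over the list alone, against 3 without wild-type replicate 3, knockout replicate 1 or knockout replicate 3. The basal median was 0.40 (adjusted p = 0.273 with an estimated correlation), 0.24 without wild-type replicate 1 and 0.71 without wild-type replicate 2. Krt14, a basal keratin, had a log2 fold change of 1.26 (SE 0.22, adjusted p = 0.0705, edgeR). Of 24 desmosome and adherens junction genes, 0 were called with edgeR, 8 were higher at an unadjusted p under 0.05, and the likelihood ratio test called 2 and DESeq2 3. Adjusted over the list alone 3 rose, 14 without wild-type replicate 2 and 0 without wild-type replicate 3, knockout replicate 1 or knockout replicate 3 (median 0.29, adjusted p = 0.285 with an estimated correlation). Without wild-type replicate 1 that median was 0.19 and without wild-type replicate 2 it was 0.53, and 1 junction gene rose in each of these fits. The tight junction list had 2 of 23 genes that rose, Cldn6 and Cldn7, and 8 adjusted over the list alone (median 0.33, adjusted p = 0.273 with an estimated correlation). The tight junction genes that rose numbered 0 without wild-type replicate 3, knockout replicate 1 or knockout replicate 3, and 1 without knockout replicate 2. Adjusted over the list alone they numbered 3 without wild-type replicate 3 and 4 without knockout replicate 1. With libraries scaled on the pan-epithelial list, the medians of the spinous, basal, junction and tight junction lists were -0.19, -0.04, -0.19 and -0.18, above the median of all genes at -0.528, and that of the periderm list was 0.4. Adjusted over the list alone, 9 periderm, 3 spinous, 0 basal, 2 pan-epithelial, 2 junction and 2 tight junction genes then rose, and 2, 3, 0, 2, 0 and 1 fell. The scaling shifts all genes by about the same amount, so lists above the median of all genes before it stay above it. That position is thus no separate result. The basal, junction and tight junction lists also share members with the scaling list, such as Krt14, Cdh1 and Cldn7.

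Wound-edge keratins rose within the list of epithelial migration genes, and planar cell polarity genes did not pass the test. Of 28 migration and wound front genes, 4 rose and 0 fell, and 12 rose adjusted over the list alone. The 4 were Krt17, Krt6a, Krt16 and Krt6b, which are keratins and also stand in other lists. The list median was 0.23 (camera adjusted p = 1.57e-20, and adjusted p = 0.17 with an estimated correlation), 0.35 without wild-type replicate 2 and -0.26 with pan-epithelial scaling, which put the median of all genes at -0.528 and left 4 rising adjusted over the list alone. The number that rose was 1 without wild-type replicate 3, and adjusted over the list alone it was 7 without wild-type replicate 3, knockout replicate 1 or knockout replicate 3. Of 29 planar cell polarity genes, 0 were called with edgeR, and the likelihood ratio test and DESeq2 each called 1. At an unadjusted p under 0.05, 3 were higher and 0 lower. Adjusted over the list alone 1 rose, and the camera test gave an adjusted p of 0.0852 (0.513 with an estimated correlation). Fzd6, a frizzled receptor of that pathway, went from 23 ± 4.51 to 37.8 ± 2 CPM (SD, n = 3, adjusted p = 0.128, edgeR). The planar cell polarity list passed the camera threshold without wild-type replicate 2 (adjusted p = 0.00245), without knockout replicate 1 (0.0492), with no filter (0.0411), with the transcript length term (0.0133), with the Y-linked term (0.000668) and without wild-type replicates 2 and 3 together (0.000173). Among 18 genes linked to GRHL3 in the literature, Krt6a alone rose, with 6 adjusted over the list alone (median 0.12, adjusted p = 0.273 with an estimated correlation), and the median was -0.33 with pan-epithelial scaling, where 1 rose adjusted over the list alone. It was 0.01 without knockout replicate 1, 0.22 without knockout replicate 2 and 0.43 without wild-type replicate 2. Of these genes 2 rose without wild-type replicate 1 or wild-type replicate 2, and 3 adjusted over the list alone without wild-type replicate 3 or knockout replicate 1. Of 27 alarmin and cytokine symbols listed, 14 were tested. Among these 14 genes, Krt16 and Krt6b rose and Serpinb3a fell, with 3 higher and 1 lower adjusted over the list alone. The alarmin median was 0.48 (camera adjusted p = 0.273 with an estimated correlation), 0.25 without knockout replicate 1 and -0.06 with pan-epithelial scaling. Adjusted over the list alone 6 alarmin genes rose without knockout replicate 2. In that list 1 rose and 0 fell without wild-type replicate 2, knockout replicate 1 or knockout replicate 3, and Serpinb3a was not called without knockout replicate 2. Krt6a was not called without wild-type replicate 3, when neither the GRHL3-linked nor the alarmin list had a member past the threshold.

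Of 14 bone genes, Smpd3 fell and 0 rose, and 7 fell adjusted over the list alone. The mean log2 CPM of the list was 2.53 in wild-type replicate 2, near the knockout libraries at 2.15 to 2.37, and 4.03 and 3.72 in wild-type replicates 1 and 3. All 14 had negative fold changes, with a median of -0.83 (camera adjusted p = 1.64e-13, and adjusted p = 0.17 with an estimated correlation). Ibsp, which encodes bone sialoprotein, measured 95.9, 0.642 and 65 CPM in the wild-type libraries and 0.304, 0.948 and 1.58 CPM in the knockout libraries (adjusted p = 0.219, edgeR). Sp7, an osteoblast transcription factor, went from 13.8 ± 4.14 to 6.66 ± 1.8 CPM (SD, n = 3, adjusted p = 0.225, edgeR). Of 23 cartilage genes, 0 were called with edgeR, 2 with the likelihood ratio test and 3 with DESeq2, and 11 were lower at an unadjusted p under 0.05. Of the cartilage genes 8 fell adjusted over the list alone, and 22 had negative fold changes. Their median was -0.49 (camera adjusted p = 9.55e-16, and adjusted p = 0.198 with an estimated correlation). Col10a1, the collagen of hypertrophic cartilage, measured 98.6, 25.7 and 90.8 CPM in the wild-type libraries and 11.2, 19.3 and 5.35 CPM in the knockout libraries (adjusted p = 0.158, edgeR). The number of cartilage genes that passed over the list alone was 3 without wild-type replicate 2, 2 without wild-type replicate 3, 1 without knockout replicate 1 and 0 without knockout replicate 3, where the cartilage median was -0.32. Smpd3 was not called without wild-type replicate 3, knockout replicate 1, knockout replicate 2 or knockout replicate 3, and 4 bone genes fell without wild-type replicate 2. With pan-epithelial scaling, where the median of all genes was -0.528, 8 bone and 13 cartilage genes fell, and 14 and 22 adjusted over the list alone, at medians of -1.42 and -0.99.

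**Figure D3:**
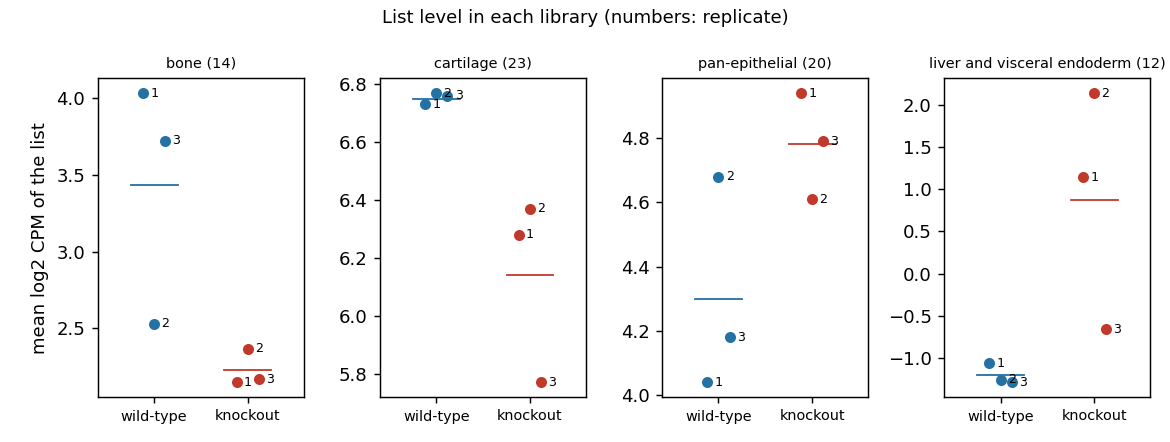
Mean log2 CPM of the members of 4 lists in each library, with replicate numbers beside the points and group means as lines (n = 3). The bone list lies at 2.53 in wild-type replicate 2, near the knockout libraries at 2.15 to 2.37, and the liver list stands at 1.14 and 2.14 in knockout replicates 1 and 2.

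Markers of other tissues and of sex also differed between libraries. Alb and Afp, plasma proteins of fetal liver and visceral endoderm that were chosen after their values were seen, measured 12.6 and 16.1 CPM in knockout replicate 1, 30.6 and 37.7 CPM in knockout replicate 2, and 1.8 and 2.6 CPM in knockout replicate 3. In the wild-type libraries Alb lay between 1.09 and 1.37 CPM and Afp between 0.987 and 1.36 CPM. Without knockout replicates 1 and 2 together, 21 genes changed, 18 of them among the 73, with the spread taken from the wild-type libraries alone. Ddx3y, Eif2s3y, Kdm5d and Uty, genes of the Y chromosome, summed to 290 and 341 CPM in wild-type replicates 2 and 3. They summed to 5.36 CPM in wild-type replicate 1 and to 3.37, 4.11 and 4.43 CPM in the knockout libraries. Without wild-type replicate 1, Y-linked expression thus followed genotype, and all 4 of these genes were called lower (edgeR). With a term for Y-linked expression 108 genes changed, 30 of them among the 73. Its genotype difference rested on wild-type replicate 1, the only wild-type library without Y-linked expression, against the knockout libraries. Leaving out wild-type replicates 2 and 3 together is in effect the same comparison, so these fits are not separate results. The term gave medians of 1.4 for the periderm, 0.93 for the junction, -1.36 for the bone and -0.4 for the cartilage list, against 0.89, 0.29, -0.83 and -0.49. With that term, camera no longer called the barrier lipid list (median 0.05, adjusted p = 0.541) or the endothelial (0.2), leukocyte (0.747), Schwann cell and melanocyte (0.344) and immediate early (0.747) lists, and it called the planar cell polarity (0.000668) and appendage and Merkel cell (0.0326) lists higher and the skeletal muscle list lower (4.99e-07). Without wild-type replicates 2 and 3 together 94 genes changed, 18 of them among the 73, with the spread taken from the knockout libraries alone. In that fit camera did not call the same 5 lists (barrier lipid, endothelial, leukocyte, Schwann cell and melanocyte, immediate early; adjusted p = 0.593, 0.225, 0.727, 0.366 and 0.727) or the alarmin list (0.113), and the leukocyte direction was lower in this fit and with the Y-linked term.

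Most of the mesenchyme and growth lists showed no difference that passed the tests. Of the 26 lists, 18 were called with the preset correlation, 15 higher and 3 lower, and 0 with an estimated correlation or with fry. At an unadjusted p under 0.05, 4 lists passed with an estimated correlation and 6 with fry. The immediate early list was called higher, with Egr2 its only member that rose (median 0.19, adjusted p = 0.299 with an estimated correlation). Without wild-type replicate 3 that median was 0.06, and without wild-type replicate 2 or knockout replicate 3 it was 0.12. In the immediate early list 3 members rose without wild-type replicate 1, and 10 adjusted over the list alone, against 5 with all libraries. Over the list alone 1 rose without wild-type replicate 2, wild-type replicate 3, knockout replicate 1 or knockout replicate 3 or with pan-epithelial scaling, and 3 without knockout replicate 2. Egr2 was not called without wild-type replicate 2 (adjusted p = 0.15, edgeR), wild-type replicate 3 (0.271), knockout replicate 1 (0.185) or knockout replicate 3 (0.147). The erythroid, endothelial, leukocyte, and Schwann cell and melanocyte lists were called higher with no member past the threshold in the edgeR quasi-likelihood test. At an unadjusted p under 0.05, 4, 2, 2 and 2 of their members were higher. In the Schwann cell and melanocyte list 1 rose adjusted over the list alone, and the likelihood ratio test and DESeq2 each called 1. The medians of these 4 lists were 0.29, 0.12, 0.12 and 0.26, with camera adjusted p = 0.299, 0.285, 0.608 and 0.237 with an estimated correlation. With pan-epithelial scaling these medians were -0.19, -0.38, -0.4 and -0.23 and that of the immediate early list -0.37, all above the -0.528 of all genes. Under that scaling camera kept the call and direction of each called list except the endothelial (adjusted p = 0.387). Camera compares a list with all other genes, so a shift common to all genes largely cancels. Neither the kept calls nor medians above that of all genes therefore test a higher epithelial share. The erythroid median was 0.48 without wild-type replicate 2, 0.19 without wild-type replicate 3, 0.44 without knockout replicate 1 and 0.18 without knockout replicate 3. The leukocyte median was 0.25 without wild-type replicate 1, 0.07 without wild-type replicate 3, 0.04 without knockout replicate 1 and 0.23 without knockout replicate 2. The leukocyte call was lost without wild-type replicate 3 (adjusted p = 0.532, camera), knockout replicate 1 (0.679) or knockout replicate 3 (0.0779), with no filter (0.0509), effective length offsets (0.0565) or the transcript length term (0.0736), and the endothelial call without knockout replicate 3 (0.101). Camera gave no call for dermal mesenchyme (adjusted p = 0.626), tendon (0.636), skeletal muscle (0.703), proliferation (0.563), interdigital BMP, retinoid and cell death genes (0.703), hypoxia and glycolysis (0.127), or appendage and Merkel cell genes (0.0517). The tendon list had a median of -0.09 and a mean of 0.01, and single libraries left out gave medians from -0.18 to 0.21. Camera called skeletal muscle higher without wild-type replicate 1 (adjusted p = 0.0199) and lower without wild-type replicate 2 (0.0391) or knockout replicate 3 (0.000508) or with the Y-linked term (4.99e-07). With pairs of libraries left out it was called higher without knockout replicates 1 and 2 (1.55e-05), as was tendon (0.000772), and lower without wild-type replicates 2 and 3 (3.59e-06). Camera called tendon lower without knockout replicate 3 (0.0121), hypoxia higher without wild-type replicate 1 (0.0035), and appendage genes higher without wild-type replicate 2 (0.00238) or knockout replicate 2 (0.0217). Appendage genes were also called higher with RLE size factors (0.0485), library size alone (0.0486), no filter (0.0419), the transcript length term (0.0357), the Y-linked term (0.0326) and pan-epithelial scaling (0.017). Slc2a1, the glucose transporter GLUT1, rose within the hypoxia list from 136 ± 6.18 to 201 ± 10.1 CPM (SD, n = 3). The Slc2a1 call was lost without wild-type replicate 2 (adjusted p = 0.119, edgeR), wild-type replicate 3 (0.264), knockout replicate 1 (0.281), knockout replicate 2 (0.126) or knockout replicate 3 (0.188).

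**Figure D4:**
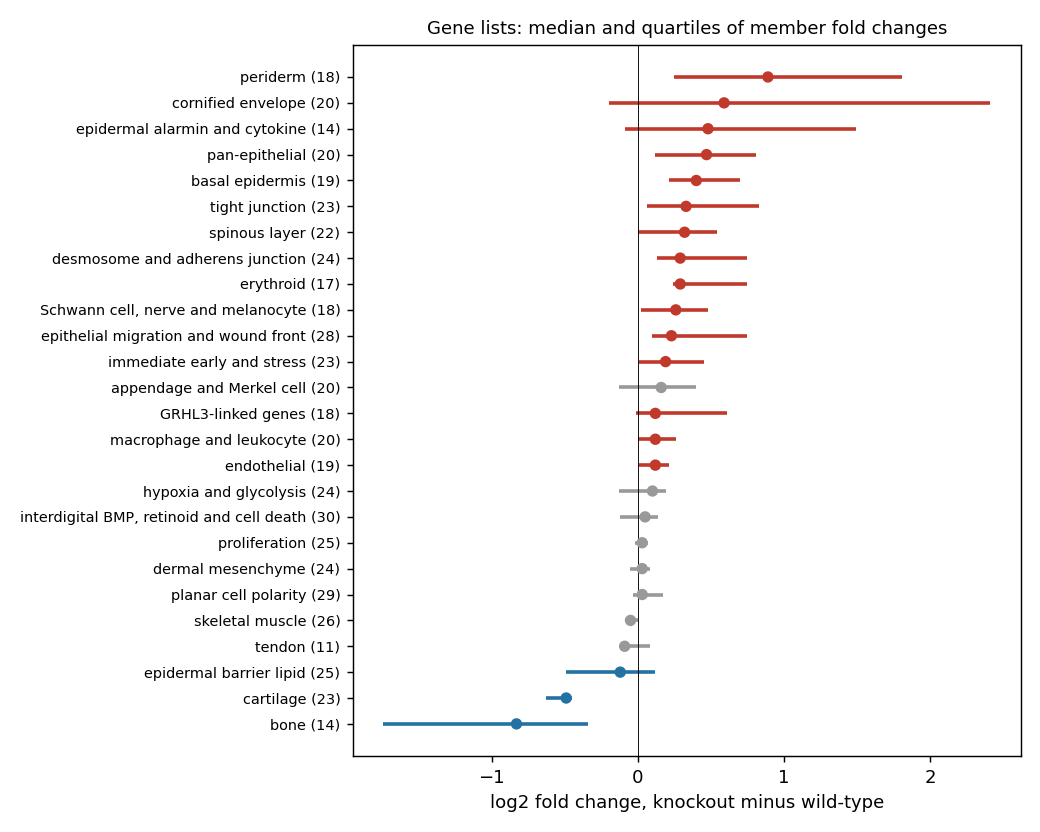
Median (points) and quartiles (lines) of the log2 fold changes, knockout minus wild-type, of the members of 26 gene lists, with the number of genes tested in parentheses. Red and blue lists were called higher and lower by camera with a preset correlation, and 0 were called with an estimated correlation. The periderm list has the highest median, 0.89, and the bone list the lowest, -0.83.

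The authors' deposited table listed 228 genes at an FDR under 0.05, 161 higher and 67 lower in the knockout. Of these, 223 were tested here, all 223 had the same sign, and 68 were also among the 73 called genes. The 5 others, Dsg4, Ubd, Gsta2, Sprr2a3 and Muc16, are not listed in the authors' deposited table and were named after their values were seen. In the authors' deposited table Grhl3 had a log2 fold change of -3.14 and Krt17 one of 3.31. The authors' deposited table and the fit made here gave log2 fold changes within 0.05 of each other for 917 of 928 shared genes. The table holds likelihood ratios, and the likelihood ratio test of edgeR, run here after this was seen, called 260 genes, including all 223. Both rest on the same 6 libraries, so neither is independent of the other. The shared calls numbered 116 without wild-type replicate 1, 39 without wild-type replicate 2, 10 without wild-type replicate 3, 17 without knockout replicate 1 and 22 without knockout replicate 3.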

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

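The likelihood ratio test, robust dispersion, the Y-linked and transcript length terms, the removal of library pairs and pan-epithelial scaling were chosen after the data were seen, and the other settings before. The 73 changed genes became 118 with no filter, 44 with effective length offsets (40 higher, 4 lower), 45 with limma-voom, 250 with the exact test, 299 with DESeq2, 19 at an FDR under 0.01, 260 with the likelihood ratio test and 203 with a transcript length term. All 73 were among the genes of the no filter, exact, DESeq2, likelihood ratio and length term fits. They became 21 without knockout replicates 1 and 2 together, where the remaining knockout library was assumed to vary like the wild-type libraries. Scaling on the pan-epithelial list gave 331 genes, 70 higher and 261 lower against 59 and 14, and gave a median of -0.528 over all genes, against -0.004. Leaving out single libraries gave 10 to 206 genes, the 206 without wild-type replicate 1, where genotype followed Y-linked expression. A test per transcript called 1 of 47536 transcripts. Counts between 55 and 108 came from other scalings, the stricter filter, robust dispersion, the Y-linked term, a fold threshold and the removal of wild-type replicates 2 and 3. The labels do not say whether the replicate numbers pair samples. Same-numbered deviations from the group means correlated at -0.32, -0.15 and -0.2, which gave no sign of pairing but cannot exclude it. With the replicate block, 47 genes changed, 40 of them among the 73, and no sample correlated best with its own number. All of the 73 genes that were tested kept their sign in each gene-level setting. Since their groups did not overlap, only a changed scaling could readily have reversed a sign.

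Grhl3 kept its direction throughout, at log2 fold changes from -2.26 to -3.54. It was no longer called with limma-voom (-2.99), robust dispersion (-3.14), the test per transcript (-3.09) or without knockout replicates 1 and 2 together (-3.15), and single libraries left out gave -3.43 to -2.46. Its adjusted p ran from 1.7e-10 with the likelihood ratio test to 0.635. The 18 list calls became 0 with an estimated correlation and 0 with fry, and lay between 14 and 21 otherwise. The 68 genes shared with the authors' deposited table became 217 with the exact test, 108 with no filter, 223 with the likelihood ratio test, 0 per transcript, and 10 to 116 with single libraries left out.

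For the genes named by the rule other than Grhl3, 1621 values under alternatives kept direction and side of the threshold, 128 lost the call, 101 gained one and 29 reversed. This tally left out the exact test, robust dispersion, other thresholds and the test per transcript. It also left out the Y-linked and transcript length terms and the removal of library pairs. None of the reversed genes was among the 73. Pan-epithelial scaling reversed 25, which its lower median over all genes accounts for. Those reported here were Grhl1 (-0.13), Grhl2 (-0.1), Vangl1 (-0.14), Prickle2 (-0.31), Fjx1 (-0.33), Bmp7 (-0.27), Ptx4 (0), Kera (-0.2), Pdgfrb (-0.36), Pax7 (-0.27), Myf6 (-0.28), Cdh5 (-0.23), Tek (-0.18), Flt1 (-0.32), Pecam1 (-0.35), Kit (-0.2), Lyz2 (-0.27), Ngfr (-0.25), Foxd3 (-0.06), Mcm2 (-0.36), Mcm5 (-0.37), Mcm3 (-0.4), Btg2 (-0.1) and Ndrg1 (-0.06). Leaving out single libraries gave -0.4 to 0.01 for Thbs2, -0.03 to 0.45 for Pax7, -0.04 to 0.67 for Myf6 and -0.51 to 0.22 for Tnnc2. For the other changes the cause was not tested. At this depth and number of libraries, most changes of 1.5-fold would be missed, since simulated ones were recovered in 19.4% of cases.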

Other observations

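The chance counts of genes and lists were planned before the data were examined, and the other tests in this part were chosen after the results were seen. Several genes outside the lists also rose. They were chosen after their values were seen. Edn1, which encodes endothelin 1, rose from 3.09, 3.65 and 2.99 CPM in wild-type to 12.6, 8.21 and 9.64 CPM in knockout libraries. Tagln, an actin-binding protein of contractile cells, measured 34.3, 24.4 and 21.6 CPM in wild-type and 103, 58.6 and 81.8 CPM in knockout libraries, and F2rl1, a receptor cleaved by serine proteases, had a log2 fold change of 1.6. A group of neighbouring genes on chromosome 3, Aadacl2, C130079G13Rik and Gm9696, fell, with log2 fold changes of -4.33, -3.96 and -3.34. Aadacl2 measured 0.898, 4.19 and 2.51 CPM in wild-type and 0.142, 0.0421 and 0.182 CPM in knockout libraries.

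The 6 libraries can be divided into 3 and 3 in 10 ways, which is too few for a share under 0.05. The genotype division gave 73 genes, and the highest of the other divisions 4, so 1 of the 10 gave as many. For gene lists, the genotype division gave 18 calls and the highest other 19, so 2 of the 10 gave as many. The other divisions gave 3 to 19 calls, among them 16 and 17. Camera with the preset correlation thus also called many lists in divisions that mix the genotypes.

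A higher share of epithelium in the knockout libraries would lift the periderm and pan-epithelial lists, which share 0 genes, by about as much. The mean log2 CPM of the periderm list minus that of the pan-epithelial list was -0.32, -0.36 and -0.36 in the wild-type and 0.55, 0.21 and 0.41 in the knockout libraries, a difference of 0.74 with a pooled SD of 0.12 (0.69 and 0.14 with medians of the members), which argues against such a share as the whole cause for the periderm list. With libraries scaled on the pan-epithelial list, 45 of the 59 rises were still called, at a median log2 fold change of 2.43 against 2.99 before. This argues against such a share as their whole cause. For the other 14, whose median went from 1.21 (median SE 0.16) to 0.68 (0.27), the call ended with a smaller fold and a larger error. Of these 14, 10 still lay over 2 standard errors above 0, without adjustment for the number of genes. For the 14 as a set, the share cannot be told apart from genotype. A larger share of periderm within the epithelium and embryo sex stay open: 59 of 59 rises in wild-type replicate 1, which lacked Y-linked expression like the knockout libraries, lay below all 3 knockout libraries, but this is a single library and the genes were called with it.

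The lower bone and cartilage genes may reflect younger knockout embryos. Embryonic beta-globins made up 10.41% ± 2.17 of beta-globin counts in wild-type and 10.66% ± 2.13 in knockout libraries (SD, n = 3), a difference of 0.26 percentage points inside the spread, so age cannot be told apart from genotype by this clock. Of 20 bone and cartilage genes that were lower at an unadjusted p under 0.05, all 20 lay above the 3 knockout libraries in wild-type replicate 1, 15 in wild-type replicate 2 and 19 in wild-type replicate 3. The 20 genes were chosen for being lower in the knockout in these same libraries, so such positions are largely built in. With a single Y-negative wild-type library, embryo sex cannot be told apart either. Differences in where the tissue was cut were not tested.

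Some features were all or none, at up to 3 counts in each library of a group and at least 20 in each of the other. Rpl9-ps6 (chromosome 19) had 5850, 5607 and 5373 counts in the wild-type libraries and 0 in each knockout library, at least 6792-fold lower against a floor of 3 counts over the group. The total of Rpl9 and its pseudogenes differed by 182.3 CPM, knockout minus wild-type, with a spread of 181 CPM, so reads moved between near-identical copies cannot be told apart from a change of the gene. By genotype 5 genes were all or none, and 4 were in the division of wild-type 1 and 3 with knockout 2 from the rest, the highest of the others. All 5 (Rpl9-ps6, Gm8162, Atp6v1c2, Muc16, Sprr2a3, named after their values were seen) lay more than 20000000 bases from Grhl3 or on other chromosomes, which argues against a linked segment for them, and the window held 4 called genes among 529 tested, against 2.2 expected by chance (Fisher's exact test, two-sided, p = 0.289). Of single transcripts, 68 were all or none by genotype, but 4 of the 10 divisions gave as many, up to 254 for wild-type 1 with knockout 2 and 3, the 3 libraries with the lowest mean transcript length per count (3148, 3385 and 3347 bases). Isoform assignment that varies between libraries whatever their genotype is a candidate explanation for such transcripts.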
